A study of Mus musculus with 28 samples.

How the data were processed

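The series holds 28 samples of bone marrow-derived dendritic cells, 26 RNA libraries and 2 libraries of ribosome footprints. RNA was poly(A)-selected and strand-specific, per the labels' protocols, and came from cells at 0 h and at 1, 2, 4, 6, 9 and 12 h with LPS or mock stimulation. RNA values are deposited in TPM, which the authors computed with RSEM 1.2.3 after alignment with Bowtie 0.12.7 to the mouse build mm9, per the submitters' processing notes. The footprint table is deposited as values that were taken as TPM because each column sums to 1000000. Its reads were aligned with Bowtie2 and TopHat2, per the submitters' processing notes, which give no versions. The descriptions of the 4 h samples name a column with hour 5, while their titles, time fields and the table say 4, and 4 h was used. The 0 h columns appear under both arm names, and the 2 repeats were identical, so each 0 h library was used once.

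Both tables list a selection of genes, 3147 for RNA and 6250 for footprints, and 363 and 750 of these carry several names joined by a semicolon, which were kept as given. TPM holds no read depth, so no counting error or detection floor could be given per sample, and precision rests on the spread between the 2 libraries of each group. Only values relative to the listed genes are compared, since each column has a fixed total. Genes with at least 1 TPM in at least 2 libraries were kept, which kept all 3147. Values were transformed to log2 of TPM plus 1, a scale that understates the change of weakly expressed genes.

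Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group (13 groups, 13 residual degrees of freedom) and a variance trend with abundance. Contrasts were LPS minus mock at each of 6 times, their joint F test, the early mean (1 h and 2 h), the late mean (6 h, 9 h and 12 h), late minus early, and mock minus 0 h. Calls used Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors of log2 fold changes are moderated standard errors, and errors of TPM are standard deviations. Footprints were compared with 0 h RNA over 2739 shared genes after each library was centred on its median gene. Gene lists were tested with camera in limma at a preset correlation of 0.01 and again with an estimated one. Of 28 lists fixed by hand from general knowledge, the 24 with at least 5 measured members were tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

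Groups, contrasts, thresholds, lists, alternatives and the rule for naming genes were fixed before the data were examined, except for settings and tests said to be chosen later. The rule names the 12 largest rises and 12 largest falls over the time course among genes past the F test whose LPS and mock libraries do not overlap. It also names the 3 largest each way at each time, 3 members and the most abundant member of each list, the 6 largest each way for late minus early, the 8 highest and 8 lowest footprint ratios, and positive controls of LPS stimulation. Not every gene named by the rule is printed.

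Each step was tested on simulated data of the same layout with genes changed 1.5-fold, 2-fold and 4-fold. For the late effect and the F test over the time course, the change was put into all 6 LPS times alike. It was put into the late times alone for late minus early, and into 6 h alone for the comparison at 6 h. The late effect recovered 62.7%, 85.1% and 100% of the changed genes, and the comparison at 6 h 10.4%, 44.8% and 87.9%. The F test over the time course recovered 59.7%, 82.1% and 100%, late minus early 14.9%, 62.7% and 87.9%, and footprints against RNA 0%, 0% and 37.9%. False calls made up 0% to 6.59% of calls. In the simulated list test the 1 shifted list was called and 0 others. Simulated genes varied independently of each other, so this cannot show how often lists whose members vary together are called falsely. Simulated libraries also shared no difference by replicate number, unlike the real ones.

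Alternatives were pseudocounts of 0.1 and 5, a minimum of 10 TPM, median-ratio rescaling, quantile normalization, a replicate term, fits to the compared groups alone, an added 2-fold threshold, other list settings and leaving out each library. Gene length and GC content came from a later annotation of the mouse genome than the authors used, matched by name for 3124 genes (99.27%). No coordinates were used. Trends of level with length and GC content were removed within each library as a setting chosen after seeing the data, which can also remove effects that go with length.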

Results

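Dendritic cells, the immune cells that present antigen to T cells, were grown from the bone marrow of C57BL/6J mice with GM-CSF and were stimulated with lipopolysaccharide (LPS) at 100 ng per ml or mock-stimulated. LPS is a cell wall component of Gram-negative bacteria recognised by Tlr4. Polyadenylated RNA was sequenced before stimulation (0 h) and 1 h, 2 h, 4 h, 6 h, 9 h and 12 h after it. The 26 RNA libraries formed 13 groups of 2 replicates, namely 0 h and the 6 later times of each arm. A further 2 libraries held ribosome footprints, the fragments of mRNA protected by ribosomes, of resting cells. RNA values were given for 3147 genes and footprints for 6250. Both were in TPM, length-normalized values with a fixed total per library, so sequencing depth per library is unknown. The medium was exchanged at time 0 for protein labelling, and protein measurements were not analysed here. The labels do not say whether the 2 replicates of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

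The comparison of LPS with mock cells at matched times asked which transcripts respond to the stimulus and when. Interferon-stimulated genes rose most. Rsad2, which encodes the antiviral protein viperin, stood at 11317 ± 988 against 16.5 ± 5.67 TPM at 6 h (SD, n = 2), a log2 fold change of 9.37 ± 0.55 (SE). Ifit3, Cmpk2, Oasl1, Ifit1, IIGP;Iigp1 and Isg15 also had their largest log2 fold changes at 6 h, of 9.08 ± 0.67, 9.00 ± 0.48, 8.46 ± 0.50, 8.39 ± 0.39, 7.04 ± 0.56 and 7.01 ± 0.33. That of Ifit1 was 8.34 at 4 h, within its error. Sizes of folds from weakly expressed genes depend on the 1 TPM added before the logarithm. With 0.1 and 5 added, Ifit3, with 1 mock library of 6 h at practically 0, stood at 10.85 and 7.56 and IIGP;Iigp1 at 7.75 and 5.71, and with 5 added Cmpk2 and Oasl1 stood at 8.28 and 7.38. Without mock replicate 1 and 2 of 6 h, Ifit3 was 10.40 and 7.76 and Cmpk2 9.65 and 8.35. In the same fits Oasl1 was 9.12 and 7.79 and IIGP;Iigp1 6.41 and 7.68. Ifit2 had its largest log2 fold change at 4 h, 8.40 ± 0.33. Cd40, a costimulatory receptor of mature dendritic cells, reached 1537 ± 273 against 2.82 ± 0.959 TPM at 6 h (SD, n = 2; log2 fold change 8.66 ± 0.42). Il1a, the gene of interleukin 1 alpha, rose by 6.41 ± 0.66 at 6 h, and Ptgs2, the inducible cyclooxygenase, by 6.82 ± 1.05 at 12 h. With 5 added, Ifit2, Cd40 and Ptgs2 stood at 7.64, 7.62 and 5.72 at these times. Il1a was 7.43 and 5.39 without mock replicate 1 and 2 of 6 h, and Ptgs2 6.06 and 7.58 without LPS replicate 1 and 2 of 12 h. Ifi205 was listed at practically 0 in both mock libraries of 9 h, so no fold is given there, and stood at 1478 ± 618 against 5.85 ± 3.28 TPM at 12 h (SD, n = 2).

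Among the positive controls fixed in advance, Il1b (interleukin 1 beta) rose by 6.26 ± 0.60 at 6 h, Irg1, which makes itaconate, by 6.17 ± 0.45 at 12 h, and Sod2, the mitochondrial superoxide dismutase, by 2.08 ± 0.15 at 12 h. Tnf, Il6, Cxcl10, Nfkbia and Tnfaip3 RNA was not analysed here. The falls were smaller. Clec10a, a C-type lectin, fell to 6.52 ± 2.49 against 184 ± 24.8 TPM at 12 h (SD, n = 2; log2 fold change -4.66 ± 0.36). Ptgs1, the constitutive cyclooxygenase, and Mrc1, the mannose receptor, had log2 fold changes of -3.89 ± 0.23 and -3.62 ± 0.27 at 12 h. At 4 h Agfg2 and Synpo stood at -4.13 ± 0.45 and -3.95 ± 0.27. At 6 h the merged row of Acap1 (mKIAA0050;BC064116;Acap1;Centb1), Apex1, Mical1 and Klc4 stood at -4.10 ± 0.39, -3.61 ± 0.73, -3.54 ± 0.37 and -3.40 ± 0.21, and at 12 h Srm and Gamt stood at -3.51 ± 0.67 and -3.49 ± 0.42. With 5 added, Clec10a, Ptgs1, Agfg2 and Synpo stood at -4.05, -3.24, -3.06 and -2.98 at these times, and Acap1, Apex1, Mical1, Klc4, Srm and Gamt at -3.49, -2.40, -2.96, -2.62, -2.59 and -2.53. Apex1 was -4.63 with 0.1 added, and -4.89 and -2.32 without LPS replicate 1 and 2 of 6 h. Mical1 was -4.06 and -3.03 in the same 2 fits, and Srm -4.47 and -2.55 without LPS replicate 1 and 2 of 12 h. Hist1h1b, a linker histone, stood at -4.19 ± 1.47 at 6 h (-3.36 with 5 added), and its call was lost after median-ratio rescaling (adjusted p = 0.062). Without single libraries of 6 h, Hist1h1b ran from -5.47 to -2.91. Over the 6 times together, 1801 of 3147 genes changed by limma's F test at an adjusted p under 0.05, and 1428 after median-ratio rescaling.

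**Figure D1:**
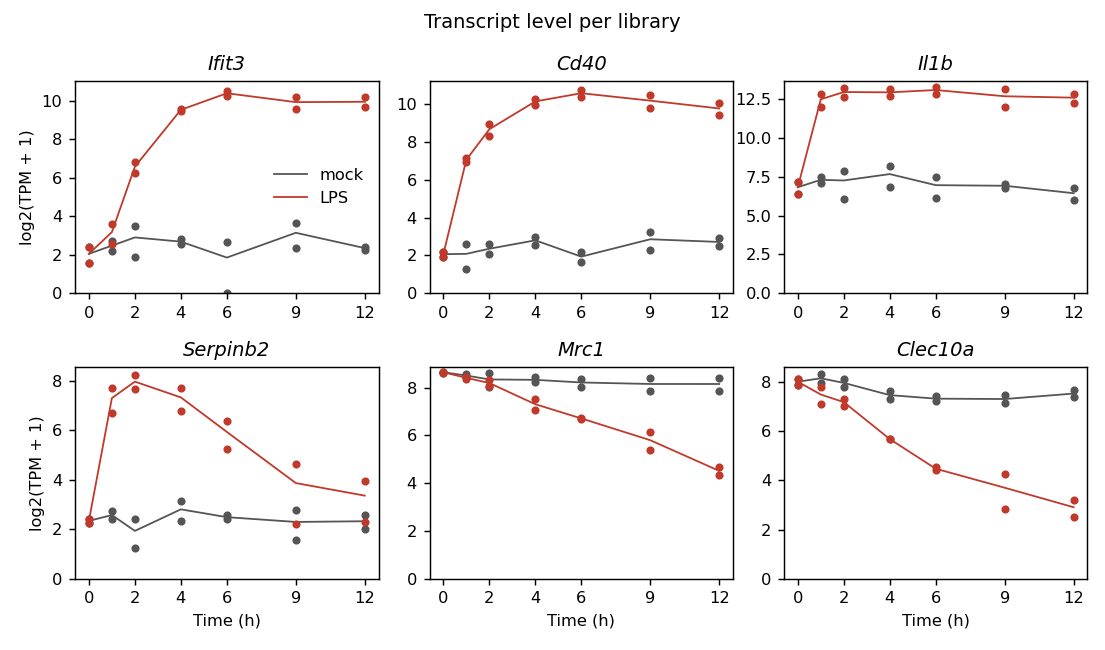
Transcript level of 6 genes per library on the log2(TPM + 1) scale against time in hours. Points are single libraries (2 per group), lines join the log2(mean TPM + 1) of LPS (red) and mock (grey) groups, and both arms start from the libraries of 0 h. Panels of Ifit3, Cd40, Il1b and Serpinb2 show rises and those of Mrc1 and Clec10a falls under LPS.

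Taken by single times, the largest rises at 1 h were those of Ptgs2, Il1b and Il1a, genes of inflammatory mediators. At 1 h Il1b stood at 5796 ± 2404 against 158 ± 28.9 TPM (SD, n = 2), and Ptgs2, Il1b and Il1a had log2 fold changes of 5.21 ± 1.05, 5.14 ± 0.60 and 5.14 ± 0.66. Junb, an immediate early transcription factor listed as AK006748;Junb, rose by 2.25 ± 0.22. Tsc22d3;Tilz3b, a glucocorticoid-induced gene, Rab19 and Nudt16 stood lower at -3.15 ± 0.40, -1.72 ± 0.46 and -1.54 ± 0.33. At 2 h Rsad2, Ifit1 and Oasl1 led with 7.55 ± 0.55, 7.04 ± 0.39 and 6.92 ± 0.50, while Tnfaip8l2, Irf2bp2 and Commd5 stood at -3.37 ± 0.38, -3.20 ± 0.57 and -2.96 ± 0.47. At 4 h Nbeal2 followed Agfg2 and Synpo among the falls with -3.39 ± 0.29. At 9 h Rsad2, Oasl1 and Clec10a stood at 7.99 ± 0.55, 7.78 ± 0.50 and -3.77 ± 0.36, and at 12 h Rsad2 and Oasl1 stood at 8.21 ± 0.55 and 7.82 ± 0.50. With 5 added, Ptgs2 and Tsc22d3;Tilz3b stood at 4.01 and -2.51 at 1 h, Oasl1 and Commd5 at 6.30 and -2.30 at 2 h, Nbeal2 at -2.22 at 4 h, and Oasl1 at 7.08 and 7.14 at 9 h and 12 h. Commd5 was -4.08 and -1.84 without LPS replicate 1 and 2 of 2 h. The calls of Ptgs2, Rab19, Nudt16, Rel and Irf4 at 1 h and of Cd14 at 2 h were each lost without 1 of the libraries compared.

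In limma tests with Benjamini-Hochberg adjustment, 103 genes rose and 25 fell at 1 h, 201 and 253 at 2 h, 275 and 918 at 4 h. The counts were 353 and 945 at 6 h, 318 and 944 at 9 h, and 315 and 843 at 12 h. The median over all genes lay at -0.05, -0.16, -0.46, -0.44, -0.44 and -0.39 on the log2 scale at these times. After median-ratio rescaling, which removes most of that shift, 111 genes rose and 33 fell at 1 h, 253 and 163 at 2 h, 445 and 405 at 4 h. The rescaled counts were 568 and 464 at 6 h, 508 and 404 at 9 h, and 526 and 436 at 12 h. With quantile normalization falls stayed ahead from 4 h on, with 112 and 79 at 1 h, 224 and 207 at 2 h, 368 and 442 at 4 h, 445 and 509 at 6 h, 417 and 518 at 9 h and 436 and 509 at 12 h. The genes that fell under both scalings numbered 405 at 4 h and 436 at 12 h. The total of 128 genes at 1 h depended on single libraries, with 52 and 76 genes without mock replicate 1 or 2 and 329 and 68 without LPS replicate 1 or 2. The total of 454 at 2 h became 267 and 255 without mock replicate 1 or 2 and 273 and 281 without LPS replicate 1 or 2. The titles number the libraries as replicate 1 or 2 but do not say what equal numbers share, so the fit holds no replicate term. Libraries did differ by number, with 845 genes higher and 1132 lower in number 2. Replicate differences correlated from 0.227 to 0.685 between LPS and mock of the same time. The fit counts these differences as spread, so its errors and counts depend on leaving the term out. With such a term the totals were 544 at 1 h (352 rose and 192 fell) and 871 at 2 h (346 rose and 525 fell).

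**Figure D2:**
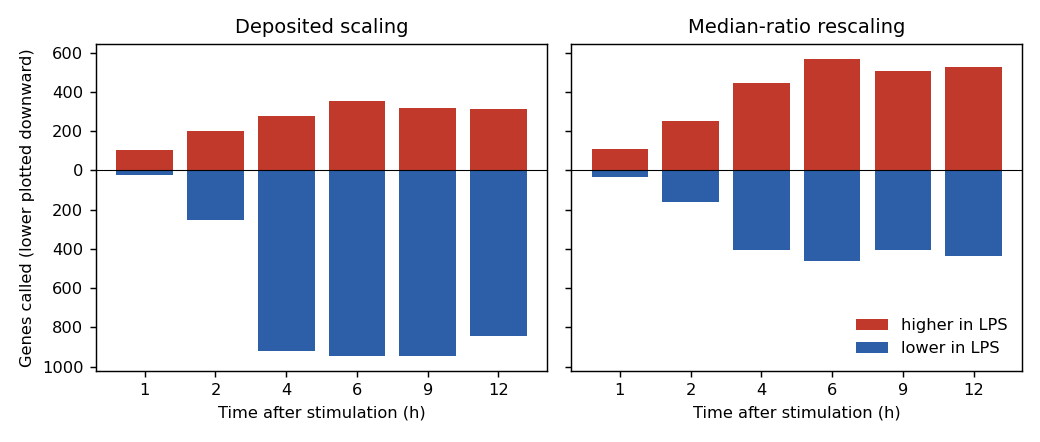
Number of genes higher (red, upward) or lower (blue, downward) in LPS than in mock cells at each time in hours, among 3147 genes tested with limma at an adjusted p under 0.05. The left panel uses the deposited scaling, with 945 lower genes at 6 h, and the right panel median-ratio rescaling, with 464.

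The early effect, the mean of 1 h and 2 h, asked which of the measured groups of genes were changed at the start of the response. The table holds 1 of 26 immediate early genes, 6 of 34 cytokines and chemokines and 8 of 24 dendritic cell maturation genes. It also holds 16 of 46 NF-kB pathway genes and 32 of 48 type I interferon response genes, so whole pathways were not ranked. The mean does not order lists in time. At 1 h and 2 h the median log2 fold change was 0.67 and 1.96 for type I interferon response and 0.31 and 2.68 for interferon-inducible GTPases. It was 1.67 and 1.85 for dendritic cell maturation, 1.365 and 2.67 for cytokines and chemokines and 0.67 and 1.03 for the NF-kB pathway. Of 32 measured type I interferon response genes, 24 rose and none fell (28 rose adjusted over the list alone), with a list median of 1.30 on the log2 scale. limma's camera test placed the list above the other genes (adjusted p = 2.2e-28, and 4.2e-05 with an estimated correlation). Of 8 dendritic cell maturation genes, 6 rose (8 adjusted over the list alone; median 1.91, adjusted p = 1.3e-11, and 6.2e-05 with an estimated correlation). Among them were Marcksl1 at 3.32 ± 0.30 and Stat5a, a signal transducer of cytokine receptors, at 3.20 ± 0.30, both at 2 h. Of 16 genes of the NF-kB pathway, 9 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.83, adjusted p = 9.7e-08, and 0.031 with an estimated correlation). It was led by Rel, an NF-kB subunit, at 3.33 ± 0.70 at 1 h and Cd14, a coreceptor for LPS, at 2.68 ± 0.84 at 2 h. Of 8 interferon-inducible GTPases 7 rose (8 adjusted over the list alone; adjusted p = 9.7e-08, and 0.015 with an estimated correlation). Of 6 cytokines and chemokines 4 rose (4 rose and 1 fell adjusted over the list alone; adjusted p = 2.6e-04, and adjusted p = 0.09 with an estimated correlation).

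Lower than other genes at 1 h and 2 h were mitochondrial ribosomal proteins, of which 11 of 37 fell (15 adjusted over the list alone; median -0.57, adjusted p = 5.0e-06, and 0.011 with an estimated correlation). The other such list was DNA replication and mitosis, of which 10 of 24 fell (14 fell and 1 rose adjusted over the list alone; median -0.51, adjusted p = 7.2e-05, and 0.015 with an estimated correlation). Oxidative phosphorylation genes (10 of 56 fell, 10 adjusted over the list alone, adjusted p = 1.7e-04) and cytosolic ribosomal proteins (5 of 73 fell, 0 adjusted over the list alone, adjusted p = 0.0052) passed with the preset correlation, with adjusted p = 0.25 and 0.17 with an estimated correlation. Across genes the early effect had a Spearman correlation of 0.325 with transcript length and -0.323 with GC content. With both trends removed, a setting chosen after seeing the data, the calls of the oxidative phosphorylation and cytosolic ribosomal lists ended (adjusted p = 0.41 and 0.44, medians -0.12 and 0.07 against -0.34 and -0.20 before), and the mitochondrial ribosomal and DNA replication lists kept theirs (adjusted p = 0.0011 and 3.1e-05, medians -0.36 and -0.57 against -0.57 and -0.51 before). Irf4, a dendritic cell transcription factor, rose by 1.59 ± 0.35 at 1 h. Granule genes of neutrophils and their precursors, markers of another cell type of the culture, had a median of -0.04 with 0 of 7 called (0 adjusted over the list alone; adjusted p = 0.88). In all, 264 genes rose and 306 fell early, against 313 and 197 after median-ratio rescaling and 300 and 363 after quantile normalization. The early count was 376 without mock replicate 1 of 1 h.

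The late effect, the mean of 6 h, 9 h and 12 h, asked which groups were changed once the response was established. All 32 type I interferon response genes rose (32 adjusted over the list alone; median 3.30, camera adjusted p = 2.3e-37, and 8.4e-06 with an estimated correlation). So did all 8 interferon-inducible GTPases (8 adjusted over the list alone; median 4.22, adjusted p = 6.4e-11, and 0.0042 with an estimated correlation). Gbp2 stood at 2727 ± 110.1 against 118 ± 5.77 TPM at 6 h (SD, n = 2), Gbp3 at 4.80 ± 0.28 and Ifi47 at 5.16 ± 0.63. Of 13 genes of MHC class I presentation and the immunoproteasome, which make and load peptides, 10 rose and 3 fell (10 and 3 adjusted over the list alone; 10 and 0 after rescaling; median 1.43, adjusted p = 4.4e-07, and 9.3e-04 with an estimated correlation). Tap1, a peptide transporter, stood at 679 ± 10.1 against 89.1 ± 0.201 TPM at 6 h (SD, n = 2). Psme2 and Tapbp had log2 fold changes of 2.13 ± 0.42 and 2.06 ± 0.23 at 9 h, and B2m (BC002288;B2m) of 1.02 ± 0.16 at 12 h. Of 8 dendritic cell maturation genes 5 rose (5 adjusted over the list alone; adjusted p = 9.9e-06, and 0.0022 with an estimated correlation).

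Of 6 cytokines and chemokines, 4 rose and 1 fell (4 and 1 adjusted over the list alone; 5 rose and none fell after rescaling; adjusted p = 2.8e-04, and adjusted p = 0.089 with an estimated correlation). The T cell attractant Ccl5 reached 40218 ± 4631 against 587 ± 133 TPM at 12 h (SD, n = 2), while Ccl6, the member with the highest mean over all RNA libraries, was the 1 that fell late (-0.44 ± 0.14, adjusted p = 0.012), a call lost after rescaling (adjusted p = 0.88). Of 16 NF-kB pathway genes 12 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 2.2e-06, and adjusted p = 0.057 with an estimated correlation), with Tank at 2.67 ± 0.35 at 6 h.

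Below the other genes late lay DNA replication and mitosis. On the deposited scaling, 4 further lists passed at the preset correlation but not with an estimated one. After rescaling, the cholesterol synthesis, mitochondrial ribosomal and oxidative phosphorylation lists kept their calls at the preset correlation (camera adjusted p = 0.0025, 0.0041 and 0.011). With an estimated correlation after rescaling they had camera adjusted p = 0.056, 0.041 and 0.54. Of 24 DNA replication and mitosis genes 22 fell and none rose (23 adjusted over the list alone; 20 after rescaling; median -1.55, adjusted p = 1.0e-05, and 0.0069 with an estimated correlation). They included the replication helicase subunit Mcm2 at -2.58 ± 0.23 (-1.96 with 5 added) and the mitotic kinase Cdk1 at -2.52 ± 0.20 at 12 h and Tubb5 at -1.36 ± 0.16 at 6 h. Of 11 cholesterol synthesis genes 10 fell (10 adjusted over the list alone; 9 fell and 1 rose after rescaling; median -1.43, adjusted p = 0.0096, and adjusted p = 0.11 with an estimated correlation). Examples were Cyp51 at 15.7 ± 5.82 against 123 ± 12.3 TPM (SD, n = 2), Mvk at -2.22 ± 0.31 and Fdps at -1.90 ± 0.36, all at 12 h, and Acat3;Acat2 at -2.83 ± 0.31 at 6 h. Of 56 oxidative phosphorylation genes 43 fell and 1 rose (43 and 1 adjusted over the list alone; 17 and 3 after rescaling; adjusted p = 0.0033, and adjusted p = 0.39 with an estimated correlation), with Ndufa12 of respiratory complex I at -1.67 ± 0.18 and Ndufb10 at -1.65 ± 0.27 at 12 h. Of 37 mitochondrial ribosomal proteins 26 fell and 1 rose (26 and 1 adjusted over the list alone; 17 and 3 after rescaling; adjusted p = 0.009, and adjusted p = 0.095 with an estimated correlation), with Mrpl12 at -1.95 ± 0.19 at 6 h and Mrps26 at -2.00 ± 0.38 at 4 h. Of 73 cytosolic ribosomal proteins 61 fell and 1 rose (63 and 1 adjusted over the list alone; adjusted p = 0.003, and adjusted p = 0.11 with an estimated correlation), with Rpl14 at -1.24 ± 0.22 at 12 h. After rescaling 8 fell and 3 rose, which ended the list's call (adjusted p = 0.14). With the trends in length and GC content removed, chosen after seeing the data, the calls of the oxidative phosphorylation, mitochondrial and cytosolic ribosomal lists ended (adjusted p = 0.055, 0.051 and 0.19). Their medians were then -0.50, -0.74 and -0.37, against -0.68, -0.83 and -0.57 without that step, so the lost calls alone do not trace the falls to length or GC content.

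**Figure D3:**
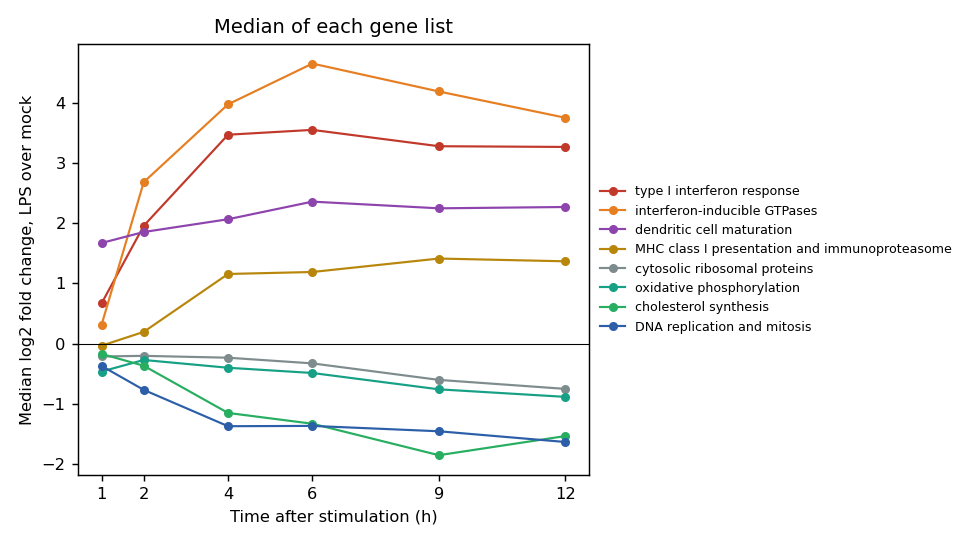
Median log2 fold change of LPS over mock for 8 of the fixed gene lists, chosen for the plot, against time in hours, on the deposited scaling, where the median over all genes lies at -0.44 at 6 h. Of the lists drawn, interferon-inducible GTPases and type I interferon response genes lie highest from 2 h on, and cholesterol synthesis and DNA replication genes lowest from 4 h on. The cytokine and chemokine list is not drawn, and its median was 4.48 at 12 h.

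Of the other 13 lists tested, none passed for the late effect, with adjusted p from 0.076 for the oxidative stress response to 0.88 for granule genes, although single members moved. After median-ratio rescaling the constitutive proteasome passed (9 of 29 rose and 0 fell, adjusted p = 0.045, and adjusted p = 0.45 with an estimated correlation), against 6 and 2 on the deposited scaling (4 and 2 adjusted over the list alone; adjusted p = 0.15, and adjusted p = 0.66 with an estimated correlation). In the oxidative stress list Sqstm1 and the peroxiredoxin Prdx1 rose by 2.07 ± 0.24 and 1.33 ± 0.23 at 12 h, and Gclc stood at -2.02 ± 0.63 at 4 h, a call lost after rescaling (adjusted p = 0.062). In glycolysis Hk2 (hexokinase) rose by 1.85 ± 0.45, Pfkl by 2.03 ± 0.53 and Ldha by 0.87 ± 0.30, and Ldhb stood at -2.26 ± 0.45, all at 12 h. The calls of Pfkl and Ldha were lost without LPS replicate 1 of 12 h. In the TCA cycle list, which also holds Irg1, Idh2 and Suclg2;Scs stood at -2.65 ± 0.43 and -2.47 ± 0.38 at 12 h (Suclg2;Scs, at 1.18 and 0 TPM under LPS, was -4.35 and -1.13 with 0.1 and 5 added), and among aminoacyl-tRNA synthetases Iars stood at -2.54 ± 0.36 at 6 h (-1.72 with 5 added), Vars at -2.01 ± 0.31 at 9 h and Dars at -1.79 ± 0.34 at 4 h. Among translation factors Pabpc4;Gm12612 stood at -1.81 ± 0.25 at 12 h and Eif2b1 at -1.54 ± 0.32 at 4 h. Among heat shock proteins Hspa1b;Hspa1a rose by 3.92 ± 1.34 at 12 h, a call lost without some single libraries of that time, and Hspa9 stood at -1.38 ± 0.17 at 6 h. Hsph1 stood at -1.52 ± 0.28 at 4 h, -1.06 at 6 h, a call lost after rescaling (adjusted p = 0.066), and 1.01 at 12 h, opposite changes that cancel in its late mean. Of lysosomal genes Npc2 rose by 1.68 ± 0.30 at 12 h and Manba stood at -2.31 ± 0.39 at 4 h, and of endoplasmic reticulum stress genes Ero1l rose by 2.20 ± 0.46 and Sec61b and Dnajc3 stood at -1.34 ± 0.25 and -1.19 ± 0.29, all at 12 h. Fcgr1, a high-affinity IgG receptor among the macrophage markers, rose by 2.42 ± 0.41 at 9 h, while Mrc1 fell, as given above, and Csf1r stood at -1.88 ± 0.65 at 4 h, a call lost after rescaling (adjusted p = 0.11). The carbonic anhydrase Car2, the erythroid marker measured, rose by 3.87 ± 0.41 at 12 h. Cd74 of the MHC class II list showed 0.58 ± 0.71 at 6 h (adjusted p = 0.53), the proteasome subunit Psma7 -0.46 ± 0.54 at 6 h (adjusted p = 0.51), the elongation factor Eef1a1 -0.39 ± 0.43 at 9 h (adjusted p = 0.5) and the chaperone Hsp90ab1 -0.71 ± 0.30 at 6 h (adjusted p = 0.065). Among granule genes, markers of another cell type, S100a9 stood at -1.76 ± 0.55 at 12 h, a call lost without any 1 of the 4 libraries compared and after rescaling (adjusted p = 0.061), and 1 of 7 rose and 2 fell late (1 and 2 adjusted over the list alone). Late, 487 genes rose and 1502 fell, around an all-gene median of -0.43, against 825 and 816 after median-ratio rescaling. They were 701 and 977 after quantile normalization.

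The difference between the phases was tested directly, as the late minus the early log2 fold change. Interferon-stimulated genes gained most. Ifit3 differed by 5.61 ± 0.62, IIGP;Iigp1 by 4.72 ± 0.51, Gm4902 by 4.38 ± 0.38, Ifitm3, which restricts virus entry, by 4.34 ± 0.70 and Cmpk2 by 4.27 ± 0.44. Ifi205 was also called, but its size depends on the value added before the logarithm, since mock libraries of 9 h were at practically 0 (4.52 as reported, 5.61 and 3.80 with 0.1 and 5 added). Serpinb2, an inhibitor of plasminogen activators, rose by 4.64 ± 0.71 at 1 h and had a late minus early difference of -3.57 ± 0.65, and the Acap1 row (mKIAA0050;BC064116;Acap1;Centb1), the complement receptor C5ar1, Nop58, Clec10a and Bzw2 had -3.34 ± 0.35, -3.19 ± 0.31, -3.17 ± 0.60, -3.02 ± 0.33 and -2.99 ± 0.45. Late values were higher for 29 of 32 type I interferon response genes (30 adjusted over the list alone; median 2.02, adjusted p = 3.4e-33, and 1.7e-05 with an estimated correlation). They were higher for 7 of 8 interferon-inducible GTPases (7 adjusted over the list alone; adjusted p = 1.8e-10, and 0.0066 with an estimated correlation) and 9 of 13 MHC class I genes with 1 lower (10 and 2 adjusted over the list alone; adjusted p = 7.2e-09, and 2.9e-04 with an estimated correlation). Late values were lower for 14 of 24 DNA replication and mitosis genes, with 1 higher (18 and 1 adjusted over the list alone; adjusted p = 4.9e-04, and 0.03 with an estimated correlation).

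Cytokines and chemokines (adjusted p = 0.031), translation factors (0.016), TCA cycle genes (0.031) and cholesterol synthesis genes (0.011) passed with the preset correlation and had adjusted p = 0.41, 0.35, 0.79 and 0.15 with an estimated correlation. The calls of the TCA cycle and cytokine lists were also lost without some single libraries, such as LPS replicate 1 and LPS replicate 2 of 1 h (adjusted p = 0.12 and 0.061). In these lists 1 of 6, 0 of 38, 0 of 24 and 0 of 11 members were higher late and 0, 13, 9 and 8 lower (adjusted over the list alone, 1, 0, 0 and 0 higher and 0, 13, 14 and 10 lower). The dendritic cell identity list passed after median-ratio rescaling (adjusted p = 0.049, and adjusted p = 0.45 with an estimated correlation) but not in the reported fit, with 2 of 5 lower on the deposited scaling (4 adjusted over the list alone; adjusted p = 0.1, and adjusted p = 0.62 with an estimated correlation). Over all genes 257 were higher late than early and 699 lower, against 418 and 331 after median-ratio rescaling and 362 and 301 after quantile normalization. Without the 1 h groups, a setting chosen after seeing the data, the total of 956 became 419.

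The mock time course asked what the culture did without LPS. No gene changed between 0 h and the 6 later mock times by limma's F test at an adjusted p under 0.05, and 35 of 3147 had an unadjusted p under 0.05. Single mock times against 0 h gave no call either, with 25 to 70 genes at an unadjusted p under 0.05. These counts lie below the share of 0.05 that would be met without any change, so the p-values may be conservative. Differences between replicate numbers count as spread in this fit, which holds no replicate term. With such a term the F test also called 0 genes. The lack of calls in these fits does not show that the culture stayed the same. Changes in simulated data of this layout were put into all 6 mock times alike. Of these, the F test recovered 84.8% of 66 genes changed 4-fold and 37.3% of 67 changed 2-fold. Recovery of a change at a single mock time was not simulated.

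Ribosome footprints were set against RNA of 0 h to compare translation between genes in resting cells. Gapdh, a glycolytic enzyme whose RNA row may share reads with its many pseudogenes, had the highest footprint to RNA ratio, 9.43 ± 0.80 on the log2 scale. Its RNA was listed at only 48.2 and 6.03 TPM in the 2 libraries of 0 h, against 7189 ± 476 TPM of footprints (SD, n = 2). The histone genes Hist1h1d, Hist1h1e and Hist2h2bb followed with 7.48 ± 0.40, 6.00 ± 0.87 and 5.88 ± 0.47. The 2 RNA libraries of 0 h differed for these genes. Without replicate 1 and 2 in turn the ratio was 10.76 and 8.09 for Gapdh, 6.89 and 8.07 for Hist1h1d, 4.54 and 7.46 for Hist1h1e, and 5.16 and 6.60 for Hist2h2bb. Most histone mRNAs carry no poly(A) tail, and the RNA libraries were poly(A)-selected. Epx and Ear6;Ear7, both eosinophil granule genes, stood at 4.86 ± 0.44 and 4.92 ± 0.38 and the tubulin Tuba1c at 3.49 ± 0.23. Ifi205 also lay above, but with RNA at 2.93 and 0 TPM its ratio is set by the value added before the logarithm and is not given. At the low end, Ftl1, the ferritin light chain, had 674 ± 93.8 TPM of footprints against 35231 ± 2383 TPM of RNA (SD, n = 2; log2 ratio -4.88 ± 0.22). Iron regulatory proteins can hold its mRNA back from translation, which was not tested here as a cause. Naca, mFLJ00067;Unc13d, Acad9;AK172713, Akap13, Rbm25, Luc7l3 and Ptp4a2 lay between -4.42 and -3.44. Of these, mFLJ00067;Unc13d, Akap13, Rbm25, Luc7l3 and Ptp4a2 lay between -5.28 and -4.05 without RNA replicate 1 of 0 h and between -3.55 and -2.65 without replicate 2.

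Of 68 cytosolic ribosomal proteins, 46 had fewer footprints per RNA than the median gene and 4 more (53 and 4 adjusted over the list alone; median log2 ratio -1.24, camera adjusted p = 5.0e-14, and adjusted p = 0.67 with an estimated correlation). Lysosomal genes (12 of 41 above, 13 adjusted over the list alone, median 0.70, adjusted p = 0.0022), macrophage markers (3 of 10 above, 7 adjusted over the list alone, median 1.02, adjusted p = 0.01) and granule genes (5 of 7 above, 5 adjusted over the list alone, median 1.81, adjusted p = 0.0022) lay above, each with adjusted p = 0.67 with an estimated correlation. Granule genes, markers of another cell type, stood lower at 0 h than in mock libraries (median difference 0.98). This was mainly so in replicate 1, with a mean log2 level of 6.28 at 0 h and 7.01 to 8.46 in mock libraries. In replicate 2 the mean was 6.56 at 0 h and 6.43 to 7.12 in mock libraries. Against RNA of 0 h and all mock times the granule list was no longer called although its median stayed above those of 21 of 24 lists (adjusted p = 0.34, a list test chosen after seeing the data). The TCA cycle, glycolysis, cholesterol synthesis and dendritic cell identity lists also lay above, with adjusted p = 0.013, 0.013, 0.023 and 0.026, and 6 of 20, 3 of 10, 2 of 9 and 3 of 5 members called (8, 5, 3 and 4 adjusted over the list alone), and each had adjusted p = 0.67 with an estimated correlation. Across the 2739 genes in both tables, 374 lay above and 356 below the median gene by limma, of which 295 and 299 differed at least 2-fold. That balance follows from centring each library on its median gene, and without centring 59 lay above and 1232 below. The total of 730 became 223 and 227 without footprint replicate 1 or 2 and 2055 and 1597 without RNA replicate 1 or 2 of 0 h. The comparison spans 2 library types, aligned with different tools, in 2 tables normalized separately, with cycloheximide in the footprint protocol. Ratios therefore rank genes within these cells only. Whether shared reads, as named for Gapdh, shape the ratios of other genes or lists was not tested.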

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

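The test of a uniform shift and the list comparisons between replicate numbers and in mock cells were chosen after the result was seen, and the interferon pattern in mock cells was noticed before its tests were written. Flagged because the late and early LPS effects differed by a direct test were 956 genes, with late minus early log2 values of 5.61 for Ifit3, 4.72 for IIGP;Iigp1, 4.52 for Ifi205 (set in part by the value added before the logarithm), 4.38 for Gm4902, 4.34 for Ifitm3, 4.27 for Cmpk2, -3.57 for Serpinb2, -3.34 for mKIAA0050;BC064116;Acap1;Centb1, -3.19 for C5ar1, -3.17 for Nop58, -3.02 for Clec10a and -2.99 for Bzw2. The lists flagged in the same way had medians of 2.02 for type I interferon response, 2.62 for interferon-inducible GTPases, 0.43 for cytokines and chemokines, 1.25 for MHC class I presentation, -0.61 for translation factors, -0.66 for the TCA cycle, -1.01 for cholesterol synthesis and -1.04 for DNA replication and mitosis. Among 100 splits of the libraries, the real one included, 1 gave as many genes for the late minus early difference (956, highest other 22), 1 for the early effect (570, highest other 134), 1 for the late effect (1989, highest other 922) and 1 for the F test (1801, highest other 910).

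Falls outnumbered rises in the late effect, 1502 to 487. The TPM total is fixed, and genes that rose late held 36.4 ± 2.54% of it in LPS libraries against 13.7 ± 0.803% in mock libraries (SD, n = 6 each), which changes the share left to the other genes by -0.44 on the log2 scale. The median late change over all genes was -0.43. A uniform shift as the whole cause is excluded, since 816 genes fell under both scalings. Rescaling puts the median gene near 0, so the balance of 816 falls with 825 rises follows in part from it. Of these falls, 304 were at least 2-fold after rescaling. With a fixed total the gain of some genes is the loss of the others, so the match of -0.44 and -0.43 cannot tell the fixed total apart from falls per cell, for which no measure is at hand.

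Libraries separated by replicate number on the second principal component, which held 14.3% of the variance, with 845 genes higher and 1132 lower in number 2. Across genes the difference had a Spearman correlation of -0.169 with GC content and 0.218 with transcript length. These values lie between the bounds set beforehand, 0.1 and 0.3, so GC and length bias cannot be told apart from other differences between the sets of libraries. Granule genes, markers of another cell type, were lower in number 2 (6 of 7, 6 adjusted over the list alone; median -1.24, adjusted p = 0.02, and adjusted p = 0.49 with an estimated correlation), and their mean was higher in number 1 in every group but 0 h, for example 8.46 against 6.65 in mock cells at 4 h. The labels name no difference between the numbers, and a different mix of cells was not tested as an explanation.

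Type I interferon response genes were higher in mock libraries than at 0 h as a list, with a median log2 difference 0.26 above that of all genes (adjusted p = 1.8e-13, and 0.0021 with an estimated correlation), although 0 of 32 passed singly (1 adjusted over the list alone). In the same contrast granule genes of another cell type stood 0.98 higher (adjusted p = 2.0e-06, and adjusted p = 0.22 with an estimated correlation). That rise lay mainly in replicate 1, with a mean log2 level of 6.28 at 0 h and 7.01 to 8.46 in mock libraries. In replicate 2 the mean was 6.56 at 0 h and 6.43 to 7.12 in mock libraries. A change in the mix of cells or a response to the medium exchange or to time in culture is not separated by the design. For the interferon list, that 1 library of 0 h stands apart is excluded, since the lower of the 2 medians without 1 of them was 0.31. The granule list was not tested in this way. Carry-over of RNA or reads from LPS libraries stays open: it would be a median of 0.658% for interferon genes and 0.393% for the other induced genes, a ratio of 1.67 that meets the bound set beforehand. The permutation p of 0.84 does not show that the 2 are equal, since the quartiles of the other genes run from -1.35% to 2.85%. Carry-over at 1 common fraction would give the same percent for each gene, while the quartiles of interferon genes ran from 0.145% to 1.91%. Rsad2, at 8718 TPM late under LPS, stood at 0.148%, and Bst2, at 4017 TPM, at 2.11%. Whether this range exceeds the spread between libraries was not tested.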

How the results depend on the processing

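The settings without the 1 h groups, without the 9 h groups, with a granule-gene covariate and with GC and length trends removed were chosen after seeing the data. Of 131 total counts of genes or lists under settings fixed in advance, leave-one-out fits apart, 111 stayed within 1.5 times the reported one. So did 13 of 14 added ones. These totals ignore direction. The late effect counts as within although 487 rises and 1502 falls became 825 and 816 after median-ratio rescaling. The mock totals, at 0 in each setting, are included. Where no cause is stated, the cause was not tested. The labels do not say that replicate numbers pair the libraries. Replicate differences correlated between groups with a median of 0.589 and 76 of 78 pairs above 0.1, the lowest being 0.05 (LPS 9 h with mock 4 h), and from 0.227 to 0.685 between LPS and mock of the same time. After group means were removed, all 26 libraries correlated best with their own number, which follows from all these correlations being positive. With a replicate block, 544 genes were called at 1 h (352 rose and 192 fell), 871 at 2 h, 1796 at 4 h, 1818 at 6 h, 1792 at 9 h, 1674 at 12 h. The block called 1058 early, 2400 late, 1545 for late minus early, 2533 by the F test, 0 in the mock course and 1025 for footprints. With only the compared groups, 21 were called at 1 h, 231 at 2 h, 411 at 9 h and 345 early, but 1149 at 4 h, 874 at 6 h and 889 at 12 h. All single-time fits of this kind leave equally few residual degrees of freedom, so these alone do not account for the uneven drops. An absolute log2 fold change of at least 1 left 293 at 2 h, 824 at 9 h, 743 at 12 h, 200 early, 863 late and 524 for late minus early. With an estimated correlation 5 lists moved late, 4 for late minus early and 0 for footprints. Footprint calls were 1291 with no centring, which keeps the offset between the tables, and 1676 against RNA of 0 h and all mock times. Without the 1 h groups, late minus early called 419. With GC and length trends removed over 3124 genes, 510 genes were called early and 2016 late, and 7 and 8 lists moved.

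Leave-one-out counts ran 52 to 329 at 1 h, 255 to 281 at 2 h, 797 to 977 at 4 h, 941 to 1104 at 6 h, 865 to 1123 at 9 h, 826 to 918 at 12 h, 376 to 703 early, 1859 to 1999 late, 778 to 1032 for late minus early, 1670 to 1895 for the F test and 223 to 2055 for footprints, and stayed at 0 in the mock course. A lone library left in a group is assumed to vary like the other groups. Of 158 named values 38 changed side of the threshold or direction in some setting. Eef1a1 at 9 h turned to 0.041 under median-ratio rescaling and ran from -0.99 to 0.21 in leave-one-out fits, and Cd74 at 6 h from -0.15 to 1.30, none of them called in the reported fit. Depth is unknown, so weakly expressed genes cannot be separated from poorly counted ones.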

Other observations

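The tests of correlation with GC content and length and of lists in the mock course and between replicate numbers were chosen after the data were seen. Cytosolic ribosomal proteins (0.08, adjusted p = 2.0e-06, and 0.043 with an estimated correlation), oxidative phosphorylation (0.08, adjusted p = 2.7e-04, and 0.39 with an estimated correlation) and the oxidative stress response (0.12, adjusted p = 1.7e-04, and 0.39 with an estimated correlation) lay above other genes in mock libraries, with 0 of 73, 0 of 56 and 0 of 18 called (0, 0 and 0 adjusted over the list alone). Between replicate numbers, TCA cycle genes (-0.38, adjusted p = 0.0033, 19 of 24 lower), glycolysis (-0.43, 0.0045, 10 of 12 lower and 1 higher), lysosome (-0.27, 0.021, 26 of 41 lower and 6 higher) and oxidative stress genes (-0.28, 0.02, 14 of 18 lower) lay below other genes in number 2, each with adjusted p = 0.49 with an estimated correlation. Adjusted over the list alone, 19, 10, 27 and 14 were lower and 0, 1, 7 and 0 higher. Mean granule gene levels were 6.28 and 6.56 on the log2 scale at 0 h and 8.22 and 6.88 in the mock libraries of 1 h, replicates 1 and 2.

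Across genes the early LPS effect had a Spearman correlation of -0.323 with GC content and 0.325 with transcript length, and the late effect -0.161 and 0.135. The hypothesis that genes with more footprints per RNA at rest keep more RNA late under LPS was tested across 2739 genes and was not borne out, with a Spearman correlation of 0.0392.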
